A study of Caenorhabditis elegans with 21 samples.

How the data were processed

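The series holds mRNA libraries of sorted 1-cell hybrid embryos, of whole worms of both parental strains and of sperm, and small RNA libraries of sperm, oocytes, embryos and worms, grown at 24 C per the labels. Embryo mRNA was either poly(A)-selected or depleted of rRNA (RiboMinus), and small RNA libraries were made after 5' polyphosphatase treatment. The labels name 21 samples, 15 of mRNA and 6 of small RNA. They form 4 groups with 3 libraries and 9 groups with 1 library. The design text names the fathers as Hawaiian males, but the labels of the worm libraries state no sex. The small RNA library of maternal-strain worms is titled N2, while its strain field gives fem-1(hc17ts)/TX189(OMA-1::GFP), by which it was grouped. The text also describes an analysis of variants that separates paternal from maternal alleles; the deposited tables hold no values by allele, so the parent of origin of an mRNA could not be read from them.

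Reads were aligned with BWA, without a version, per the submitters' processing notes; genome build and annotation are not stated. The deposited mRNA table holds RPKM values made by the authors, as its name in the sample descriptions says, and the values within a gene are whole multiples of 1 read. The deposited small RNA class tables (exons, introns, miRNA precursors, rRNA, snRNA, snoRNA, tRNA and 21U loci) hold a signal that the values show to be reads multiplied by 1 constant per library, with fractions as for reads shared between places; the authors do not explain the constant. The sense columns of the deposited mature miRNA table hold RPM values, scaled to a fixed total of mature miRNA sense reads of the same library, as their sums show. The planned scaling of miRNAs to the reads of all class tables could therefore not be used, and the deposited values were kept. Sums over 21U loci and exons are in RPM of the reads of all class tables. These totals leave out the sense reads of mature miRNAs, which were deposited only as RPM. Embryo and sperm columns were matched to samples by their titles, and the oocyte and worm columns by elimination. In each of the 9 small RNA tables, 8 columns match no sample and were not used in the comparisons.

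Whole reads were recovered from the RPKM steps for all 16865 features with a value in at least 4 of the 12 replicated libraries, which gave the depth of each library. The step was tested on simulated data, where 99.3% of 16568 solved features had the right reads. Depth was 106.29 to 136.11 M mapped reads for poly(A) embryos, 4.56 to 13.88 M for RiboMinus embryos and 31.7 to 156.1 M for worms. Replicates 1 and 2 of each group differed by no more than read sampling (mean dispersion 0.97 to 1.07, where 1 is read sampling). They were averaged as 1 sample, a change from the plan of 3 samples per group that was made after seeing the data, so each group had 2 samples.

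Groups, gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Differences were fitted with limma 3.58.1 (R 4.3.3) with a trend on log2(RPKM + 1), over 11041 genes with an RPKM of at least 1 in at least 3 of the 12 libraries, in 1 fit of all 4 groups. A gene was called at an adjusted p (Benjamini and Hochberg, two-sided) under 0.05 and an absolute log2 difference of at least 1. The comparisons were CB4856 worms against maternal-strain worms, poly(A) embryos against maternal-strain worms, and poly(A) embryos against RiboMinus embryos. On simulated data with 100 changed genes at each size, this recovered 11% of 2-fold and 62% of 4-fold changes in the first comparison, 18% and 78% in the second, and 27% and 78% in the third, with 0, 65 and 173 false calls among 10722 unchanged genes.

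Of 19119 named genes, 17922 had a unique current symbol, and the others kept the deposited name. The 15 gene lists were major sperm proteins, sperm function, oocyte and early embryo, eggshell, germ granule and small RNA pathway, vitellogenins, male soma, muscle, intestine, cuticle and hypodermis, neuron, early zygotic, replication-dependent histones, cytosolic ribosomal proteins and mitochondrially encoded genes. None of the last 12 was in the table, so 14 lists were tested with camera of limma at a preset correlation of 0.01, two-sided and adjusted over 42 tests. For single libraries, a list's median was placed among 10000 random lists matched on expression in 20 bins.

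Sperm-restricted genes had an RPKM of at least 10 in the high-purity and fog-2 sperm libraries and under 1 in each maternal-strain worm library. The planned control set held 0 genes; the comparison set of 4594 genes under 1 in all sperm and maternal-strain worm libraries was chosen after seeing the data. Small RNA sets were loci with an 8-fold difference between sperm and oocytes and at least 10 reads (21U loci) or 50 reads (exons) in the higher library; tested on simulated data with 200 loci changed each way, 145 and 150 were found and 0 were wrong. A library with 0 reads was given a floor of 3 reads. Intervals are exact 95% intervals for counting error. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

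Named genes were, in each limma comparison, the 4 largest rises and falls with a mean RPKM of at least 10 and no overlap between libraries, the 3 most abundant members of each described list, and oma-1, spe-11, msp-3, vit-2, glp-1, mex-5, fem-1 and fog-2. To these came the 10 sperm-restricted mRNAs highest in embryos, the 5 largest differences each way between sperm libraries at an RPKM of at least 50, lin-4, let-7, miR-1, miR-58, miR-71 and miR-35 to miR-42 with the 6 largest ratios each way among miRNAs at 100 RPM or more (some of these already among the former), and the 5 largest ratios each way for 21U loci and exons. Not every gene under the rule is printed where its list was not called. One exon feature under the rule, a repeat-named entry, is also not printed.

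Alternatives were pseudocounts of 0.1 and 5, no expression filter or an RPKM of at least 5, quantile normalization, median centring, only the libraries of a comparison, a replicate block, a robust fit, leaving out each sample, other thresholds, and other reference libraries. Those added after seeing the data were 12 libraries as separate samples, with and without a block, limma-voom on recovered reads, and RiboMinus detection without histones. The planned edgeR fit on recovered reads was not run.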

Results

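The series measured RNA in 1-cell embryos of Caenorhabditis elegans from a cross between worms of a maternal strain in the N2 background, fem-1(hc17ts)/TX189(OMA-1::GFP), and males of the Hawaiian strain CB4856. It also measured RNA in whole worms of both strains, in sperm and in oocytes. The 21 libraries comprised 15 mRNA libraries and 6 small RNA libraries. The mRNA groups with 3 libraries each were poly(A)-selected embryos, rRNA-depleted (RiboMinus) embryos, poly(A)-selected CB4856 worms and poly(A)-selected maternal-strain worms. The other 9 libraries stood alone: CB4856 sperm of low purity, CB4856 sperm of high purity after pronase treatment, sperm of fog-2(q71) males, and 6 small RNA libraries. Small RNA came from fog-2 sperm, N2 oocytes, hybrid embryos, embryos labelled TX189(OMA-1::GFP), CB4856 worms and maternal-strain worms.

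Depth differed widely between the groups. The poly(A) embryo libraries held 111.61, 106.29 and 136.11 M mapped reads. The RiboMinus embryo libraries held 4.58, 4.56 and 13.88 M. Depth was 34.72, 34.57 and 156.1 M in CB4856 worms and 33.91, 31.7 and 135.78 M in maternal-strain worms. In each group, replicates 1 and 2 differed by no more than read sampling would give (mean dispersion of read pairs 1.0, 1.0, 0.97 and 1.07 in the groups in the order named). Replicate 3 differed from replicate 1 by 753.44, 57.02, 22.43 and 18.76. Replicates 1 and 2 were therefore counted as 1 sample, and each group had n = 2 samples. For the middle gene, replicate 3 of the worm groups differed from replicate 1 by little more than read sampling. The median dispersion was 0.56 in both strains, against 29.63 in poly(A) embryos and 6.37 in RiboMinus embryos. The spread between worm samples was thus small. Whether replicate 3 came from separately grown worms is not known. The SDs and p-values for worms may therefore not cover differences between cultures. Mean RPKM reached 1 for 7455 genes in poly(A) embryos, 7185 in RiboMinus embryos, 10544 in CB4856 worms and 9025 in maternal-strain worms. The depth of the 3 sperm mRNA libraries is unknown. The small RNA class tables held 9.55 M reads for sperm, 8.1 M for oocytes, 5.38 M for hybrid embryos, 15.32 M for TX189 embryos, 2.23 M for CB4856 worms and 2.5 M for maternal-strain worms.

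Worms of the paternal strain were compared with worms of the maternal strain to find the mRNAs that each parent's strain could be recognised by. CB4856 worms carried large amounts of sperm mRNAs that maternal-strain worms nearly lacked. The sperm-specific family members ssp-19 and ssp-16 rose from 0.557 ± 0.124 and 0.649 ± 0.129 RPKM in maternal-strain worms to 272.3 ± 0.202 and 268.0 ± 4.14 RPKM in CB4856 worms (mean ± SD, n = 2 samples per group, as for every mean below). F58A6.9 rose from 0.162 ± 0.0382 to 208.0 ± 1.88 RPKM, and fipr-20, of a family related to fungus-induced peptides, rose from 0.347 ± 0.0168 to 236.2 ± 4.85 RPKM. These were the 4 largest rises, with log2 differences of 7.46 for ssp-19, 7.35 for ssp-16, 7.49 for F58A6.9 and 7.46 for fipr-20 on the log2(RPKM + 1) scale used throughout. Among the largest falls, F10E7.2 was at 0.16 ± 0.0454 RPKM in CB4856 worms and 91.81 ± 3.56 RPKM in maternal-strain worms, phat-3 was at 0.483 ± 0.0587 and 40.51 ± 0.507 RPKM, and Y9D1A.1 was at 0.861 ± 0.068 and 39.22 ± 0.644 RPKM. The gene retr-1 was listed at 0 in CB4856 worms and at 74.6 ± 1.53 RPKM in maternal-strain worms. Whether sequence variants of CB4856 kept reads of the genes that fell from aligning was not tested. Adjusted p for these 8 genes ranged up to 0.00061 (limma).

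Of 28 major sperm protein genes, which encode the motility protein of nematode sperm, 27 rose and 1, msp-19 (named after its values were seen), was not called, with a median log2 difference of 5.43. The count adjusted over the list alone was also 27, and camera gave adjusted p = 2.17e-20, or adjusted p = 0.0322 with an estimated correlation. Examples were msp-50 at 513.0 ± 20.7 against 3.297 ± 0.139 RPKM, msp-142 at 440.8 ± 10.4 against 2.868 ± 0.15 RPKM, msp-53 at 384.4 ± 3.65 against 3.369 ± 0.219 RPKM, and msp-3 at 158.5 ± 0.41 against 1.506 ± 0.0406 RPKM. These genes are near-identical copies, so that the value of any single member is uncertain. Of 30 other sperm function genes, 29 rose, with a median log2 difference of 3.18 (29 adjusted over the list alone; camera adjusted p = 2.32e-21, or adjusted p = 0.00772 with an estimated correlation). They included ssp-10 at 292.9 ± 3.04 against 3.534 ± 0.0296 RPKM, nspd-1 at 321.0 ± 4.99 against 2.835 ± 0.489 RPKM, and spe-11, a paternal-effect gene whose product is supplied by sperm, at 5.375 ± 0.661 against 0.133 ± 0.0294 RPKM. The member not called was spe-44, at 25.67 against 18.34 RPKM. Among 29 germ granule and small RNA pathway genes, 2 rose (2 adjusted over the list alone), namely alg-3, from 0.182 to 27.03 RPKM, and alg-4, from 0.0684 to 29.12 RPKM, which encode Argonautes of spermatogenesis. The gene ppw-1 fell, from 14.22 to 4.302 RPKM, and the list's median was -0.15 and its mean 0.14 (camera adjusted p = 0.103). Of 4 male soma genes tested, mab-3, a regulator of male development, rose from 0.262 ± 0.0159 to 5.443 ± 0.392 RPKM, and cwp-1 was listed at 0 in maternal-strain worms and rose to 3.256 RPKM. With a pseudocount of 5 none of the 4 was called (mab-3 0.99). The other members, swm-1 at 26.38 ± 0.529 against 23.6 ± 1.72 RPKM and her-1 at 0.32 ± 0.0846 against 0.076 ± 0.0358 RPKM, were not called, and camera gave adjusted p = 0.0817 for the list. The genes spe-44, alg-3, alg-4, ppw-1 and cwp-1 were named after their values were seen.

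Female germline and yolk mRNAs differed far less between the strains. None of 34 oocyte and early embryo genes was called by limma, at a median log2 difference of -0.22, which camera ranked lower (adjusted p = 0.0108, or adjusted p = 0.557 with an estimated correlation). Among them, cey-2, a Y-box RNA-binding protein gene, was at 1133 ± 23.2 against 1514 ± 28.5 RPKM. The oocyte maturation gene oma-1 was at 120.7 ± 0.446 against 195.3 ± 2.27 RPKM. The maternal strain is labelled OMA-1::GFP. Reads of this fusion in its worms or embryos could not be told apart from those of oma-1. The polarity gene mex-5 was at 1277 ± 5.8 against 1418 ± 0.303 RPKM, and glp-1, a Notch receptor gene of the germline, was at 69.02 ± 1.16 against 91.06 ± 1.04 RPKM. None of 12 eggshell genes was called, at a median of -0.3 (camera adjusted p = 0.0715). Of these, cpg-1 was at 1949 ± 21.8 against 2403 ± 18.1 RPKM and perm-4 at 3472 ± 149 against 3432 ± 89.3 RPKM. Of the 6 vitellogenins, the yolk protein genes of the adult hermaphrodite intestine, vit-3 and vit-4 fell, from 209.4 to 44.94 and from 145.3 to 40.8 RPKM (named after their values were seen). The other 4 were not called: vit-6 was at 9753 ± 22 against 8210 ± 24.7 RPKM, vit-2 at 6305 ± 29.7 against 5321 ± 24.9 RPKM, vit-1 at 1888 ± 5.13 against 1276 ± 12.6 RPKM, and vit-5 at 224.8 against 223.7 RPKM. Their median was 0.13, their mean -0.49, and camera gave adjusted p = 0.254. The sex determination genes fem-1, at 34.63 ± 0.918 against 39.14 ± 0.334 RPKM, and fog-2, at 11.79 ± 0.112 against 14.47 ± 0.189 RPKM, were not called.

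Among somatic lists, 5 of 22 cuticle and hypodermis genes rose (col-179, sqt-3, col-139, dpy-7 and col-10; camera adjusted p = 0.179). Of 22 muscle genes 1 rose (myo-3; camera adjusted p = 0.179), and 1 of 18 intestine genes fell (cpr-5; camera adjusted p = 0.309, list median 0.1, or -0.18 after quantile normalization). Of 24 neuron genes, rab-3 rose, with a list median of 0.56 (camera adjusted p = 0.0237, or adjusted p = 0.492 with an estimated correlation). Of 57 replication-dependent histones, his-60 fell from 7.774 ± 0.478 to 0.892 ± 0.0168 RPKM and his-67 also fell (camera adjusted p = 0.0237, or adjusted p = 0.171 with an estimated correlation). Of 73 cytosolic ribosomal protein genes only rpl-42 rose, and the list median was -0.08, or 0.06 after median centring (camera adjusted p = 0.0251, or adjusted p = 0.655 with an estimated correlation). Of 11 early zygotic genes, tbx-11 rose from 3.383 ± 0.0887 to 9.242 ± 0.464 RPKM (camera adjusted p = 0.255, list median 0.38, or -0.25 after quantile normalization). This call of tbx-11 ended whichever of the worm samples was left out, at log2 differences of 1.18 to 1.27 against 1.22. It also ended with pseudocounts of 5 (0.76) and 0.1 (1.42, limma adjusted p = 0.0581). Apart from tbx-11 and his-60, the members named here were chosen after their values were seen. The counts adjusted over the list alone equalled those over all genes in each of these 7 lists.

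In total, limma called 14.9% of 11041 genes in CB4856 worms (adjusted p under 0.05 and an absolute log2 difference of at least 1, two-sided). Of these calls 1463, or 89.1%, were higher and the rest lower; the higher ones numbered 587 with a pseudocount of 5 and 713 with an RPKM of at least 5 in 3 libraries. The median over all genes was 0.03; quantile normalization moved it to -0.18 with 921 higher and 577 lower (61.5% higher), and median centring to 0.17 with 1707 higher and 160 lower (91.4% higher). The labels do not give the sex of the worms in these libraries. The maternal strain carries fem-1(hc17ts), and all worms were grown at 24 C. The effect of this mutation cannot be told apart from that of strain background or sex.

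**Figure D1:**
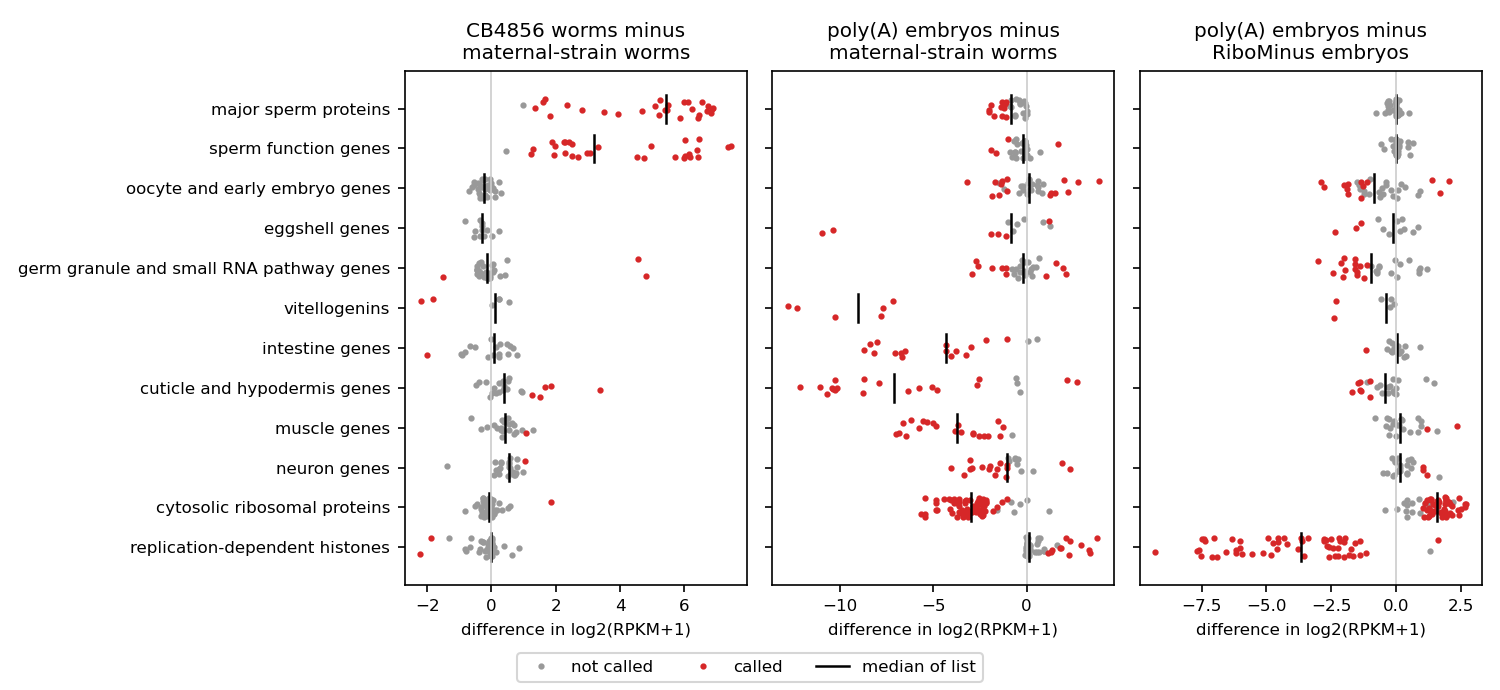
Differences in log2(RPKM + 1) of the members of 12 gene lists in the 3 comparisons (1 point per gene, red where called, black bar at the list median). The medians of major sperm proteins and sperm function genes in CB4856 worms were 5.43 and 3.18, vitellogenins in poly(A) embryos lay at a median of -9.05 against maternal-strain worms, and histones at -3.68 against RiboMinus embryos; in poly(A) embryos against maternal-strain worms, the medians of oocyte genes (0.15) and histones (0.16) lay below 0 after median centring (-0.92 and -0.91).

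The embryos were compared with maternal-strain worms to separate the mRNAs of the zygote from those of the mother's body. Most genes listed for yolk, cuticle, intestine and muscle fell in poly(A) embryos. The largest falls were those of vit-6, from 8210 ± 24.7 RPKM in maternal-strain worms to 0.145 ± 0.166 RPKM in embryos, vit-2, from 5321 ± 24.9 to 0.045 ± 0.0324 RPKM, and the cuticle collagens col-119, from 4736 ± 36.8 to 0.0512 ± 0.0112 RPKM, and col-143, from 3290 ± 144 to 0.531 ± 0.424 RPKM. The largest rises were those of Y48G1A.2, from 13.15 ± 0.887 to 653.1 ± 284 RPKM, T12G3.6, from 7.171 ± 0.187 to 362.0 ± 137 RPKM, F15A4.10, from 5.477 ± 1.02 to 236.6 ± 19.8 RPKM, and kbp-4, a kinetochore gene, from 7.744 ± 0.169 to 402.0 ± 397 RPKM. Adjusted p for these 8 genes was at most 0.00172 (limma).

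All 6 vitellogenins fell (6 adjusted over the list alone; median -9.05; camera adjusted p = 3.78e-05, or adjusted p = 0.145 with an estimated correlation). Of 22 cuticle and hypodermis genes, 17 fell and 2 rose (17 and 2 adjusted over the list alone; median -7.13; camera adjusted p = 2.09e-07, or adjusted p = 0.145 with an estimated correlation). The members that rose were sqt-3, from 8.925 to 69.08 RPKM, and dpy-7, from 0.833 to 7.396 RPKM, collagens of the larval cuticle, whereas col-124 fell from 2392 ± 28 to 1.244 ± 1.35 RPKM. Of 18 intestine genes, 16 fell (16 adjusted over the list alone; median -4.31; camera adjusted p = 3.95e-07, or adjusted p = 0.0456 with an estimated correlation). They included the protease genes cpr-6, from 864.7 ± 10.7 to 1.573 ± 0.18 RPKM, and asp-3, from 600.7 ± 10.1 to 1.108 ± 0.611 RPKM, and the actin gene act-5, from 443.1 ± 6.72 to 3.844 ± 0.98 RPKM. Of 22 muscle genes, 21 fell (21 adjusted over the list alone; median -3.76; camera adjusted p = 1.12e-08, or adjusted p = 0.394 with an estimated correlation). They included mlc-2, a myosin light chain gene, from 1696 ± 1.65 to 15.95 ± 2.44 RPKM, pat-10, a troponin C gene, from 625.1 ± 10.6 to 14.78 ± 3.14 RPKM, and act-4 from 486.2 ± 4.82 to 15.9 ± 1.28 RPKM. Of 24 neuron genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone; median -1.07; camera adjusted p = 0.000314, or adjusted p = 0.298 with an estimated correlation). Lower calls in this list numbered 8 after quantile normalization, 6 with a pseudocount of 5 and 21 after median centring. Among them egl-21, a neuropeptide processing gene, fell from 28.76 ± 0.289 to 2.839 ± 0.0269 RPKM, while snb-1, a synaptobrevin gene, rose from 83.32 ± 0.204 to 323.2 ± 72.8 RPKM and unc-119 rose from 22.37 ± 0.922 to 117.5 ± 31.7 RPKM. After median centring snb-1 (0.86) and unc-119 (1.25, adjusted p = 0.0803) were not called. The call of unc-119 also ended after quantile normalization (1.36, limma adjusted p = 0.0812). It ended as well without embryo replicate 3 (log2 difference 2.04), without maternal-strain replicate 3 (2.28), or without maternal-strain replicates 1 and 2 (2.36).

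Ribosomal protein mRNAs were also low in poly(A) embryos: 67 of 73 fell (67 adjusted over the list alone; median -2.97; camera adjusted p = 3.49e-13, or adjusted p = 0.252 with an estimated correlation). They included rps-4 from 8540 ± 19 to 318.2 ± 180 RPKM, rps-25 from 6670 ± 63.4 to 609.7 ± 396 RPKM, and rps-1 from 5469 ± 57.4 to 322.0 ± 102 RPKM. Of 12 eggshell genes, 5 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.86; camera adjusted p = 0.179), or 8 and 0 after median centring. The permeability barrier gene perm-4 fell from 3432 ± 89.3 to 0.696 ± 0.0808 RPKM and perm-2 from 2350 to 0.737 RPKM, cbd-1, egg-1 and chs-1 also fell, and egg-3 rose from 140.7 to 321.5 RPKM. The eggshell proteoglycan genes cpg-1, at 2361 ± 1194 against 2403 ± 18.1 RPKM, and cpg-2, at 1885 ± 946 against 2939 ± 37 RPKM, were not called, though cpg-2 was called lower without embryo replicates 1 and 2 (log2 difference -1.27) and after median centring (-1.8). Apart from perm-4, cpg-1 and cpg-2, these eggshell genes, and sqt-3 and dpy-7, were named after their values were seen.

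Oocyte and early embryo genes went both ways: 7 of 34 rose and 8 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.787), and their median of 0.15 became -0.51 after quantile normalization and -0.92 after median centring, with 3 higher and 15 lower. The 3 most abundant members rose: cey-2 from 1514 ± 28.5 to 6201 ± 285 RPKM, par-5, a 14-3-3 polarity gene, from 658.3 ± 12.5 to 4556 ± 1277 RPKM, and pos-1, a maternal fate regulator, from 1051 ± 13.3 to 2544 ± 542 RPKM. After median centring the log2 differences of cey-2 and pos-1 were 0.97 and 0.19 and neither was called. Neither oma-1, at 238.2 ± 66.6 against 195.3 ± 2.27 RPKM, nor glp-1, at 104.7 ± 21.3 against 91.06 ± 1.04 RPKM, was called. The level of mex-5 was 567.9 ± 364 against 1418 ± 0.303 RPKM, which was not called, but was without embryo replicate 3 (log2 difference -2.19, adjusted p = 0.0396) and after median centring (-2.55). The sex determination gene fog-2 rose from 14.47 ± 0.189 to 53.24 ± 29.3 RPKM and was not called after median centring (0.63) or quantile normalization (0.98), while fem-1, at 30.2 ± 0.000972 against 39.14 ± 0.334 RPKM, was not called. It was called lower after median centring (-1.43) and quantile normalization (-1.09). Of 29 germ granule and small RNA pathway genes, 4 rose and 7 fell (4 and 7 adjusted over the list alone; median -0.21; camera adjusted p = 0.604), which became 1 and 17 after median centring (median -1.28) and 2 and 12 after quantile normalization (-0.64). The Argonaute gene hrde-1 fell from 531.2 ± 8.56 to 250.7 ± 6.8 RPKM. The genes wago-1, at 513.3 ± 120 against 423.9 ± 12.2 RPKM, and pgl-1, a P granule gene, at 531.2 ± 340 against 664.7 ± 61.2 RPKM, were not called. However, pgl-1 was called lower without embryo replicates 1 and 2 (-1.19) and after median centring (-1.55). The members that rose, named after their values were seen, were deps-1, mut-2, ego-1 and eri-1. Of 57 histones, 12 rose (9 adjusted over the list alone; camera adjusted p = 0.0472, or adjusted p = 0.217 with an estimated correlation), with a median of 0.16 that median centring turned to -0.91, with 6 higher and 22 lower. They included his-59, from 5.813 ± 0.241 to 92.88 ± 1.56 RPKM, and his-60, from 7.774 ± 0.478 to 95.56 ± 28.3 RPKM. So did his-62, from 11.28 ± 0.0449 to 60.64 ± 12.2 RPKM. Their near-identical copies make single values uncertain.

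Early zygotic genes are transcribed mainly after the 1-cell stage. Of 11 tested, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.529), and the median of 0.1 became -0.96 after median centring. The Notch target ref-1 rose from 1.165 ± 0.00471 to 13.76 ± 0.883 RPKM, tbx-33 rose from 6.746 ± 0.465 to 20.26 ± 0.575 RPKM but was not called after median centring (0.39), sdz-38 rose and elt-3 fell, the last 2 named after their values were seen. The level of tbx-11 was 5.137 ± 2.53 against 3.383 ± 0.0887 RPKM, not called, but called higher after quantile normalization (1.01). Of 28 major sperm protein genes 12 fell (12 adjusted over the list alone; median -0.82; camera adjusted p = 0.00116, or adjusted p = 0.227 with an estimated correlation). All did so from low levels, and with a pseudocount of 5 limma called none of them. Lower calls numbered 3 after quantile normalization, 19 with a pseudocount of 0.1, 22 with limma-voom and 28 after median centring. Median centring moved every gene down by the same amount (median of all genes from 0.05 to -1.02). A gene near 0 RPKM in both groups could be called lower by this shift alone. Lower calls after median centring, here and below, therefore cannot show a fall of such genes. The gene msp-50 was at 0.0723 ± 0.102 against 3.297 ± 0.139 RPKM, msp-142 at 0.144 ± 0.203 against 2.868 ± 0.15 RPKM, msp-53 at 0.0737 ± 0.0788 against 3.369 ± 0.219 RPKM, and msp-3 at 0.0534 ± 0.0755 against 1.506 ± 0.0406 RPKM. Of 30 sperm function genes, spe-6 rose, from 0.872 to 5.018 RPKM, and 3 fell, namely nspd-1 to 0.0321 ± 0.0454 RPKM, ssp-10 to 0.509 ± 0.585 RPKM and ssq-1 to 0.0744 RPKM (1 and 3 adjusted over the list alone; camera adjusted p = 0.052; spe-6 and ssq-1 named after their values were seen), with a median of -0.18, or 0.06 after quantile normalization. Lower calls in this list numbered 0 after quantile normalization or with a pseudocount of 5, 15 with a pseudocount of 0.1, 18 with limma-voom and 27 after median centring. Paternal-effect spe-11 was at 0.0122 ± 0.00378 against 0.133 ± 0.0294 RPKM and ssp-19 was listed at 0 in embryos against 0.557 ± 0.124 RPKM; neither was called. Both were called lower with limma-voom (spe-11 -3.21, ssp-19 -5.99), after median centring (-1.23 and -1.7) and with a pseudocount of 0.1 (-1.05 and -2.7). Of the 4 male soma genes, her-1 rose from 0.076 ± 0.0358 to 2.269 ± 0.838 RPKM (not called after median centring or with a pseudocount of 5, 0.51), swm-1 fell from 23.6 ± 1.72 to 0.0611 ± 0.0864 RPKM, and mab-3 was at 0.219 ± 0.265 against 0.262 ± 0.0159 RPKM, called lower only after median centring (-1.13) among the scalings (1 and 1 adjusted over the list alone; camera adjusted p = 0.787; median -0.03, or 0.26 after quantile normalization).

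Between poly(A) embryos and maternal-strain worms, limma called 3412 genes higher and 2692 lower of 11041 (55.9% higher). The split depended on the scale: median centring shifted the median of all genes from 0.05 to -1.02, with 1553 higher and 5482 lower (22.1% higher), while quantile normalization moved it to 0.15 with 3036 higher and 2248 lower. The shift of median centring also applied to genes near 0 RPKM in both groups, so some of its lower calls can follow from it alone. On simulated data this comparison gave 65 false calls among 10722 unchanged genes, so its adjusted p-values may be too small. None of the 12 genes listed as mitochondrially encoded was in the mRNA table.

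Poly(A) and RiboMinus libraries of the same kind of embryo were compared to see which mRNAs the poly(A) selection left out. Replication-dependent histone mRNAs, which lack a poly(A) tail, fell most. The 4 largest falls were those of his-1, at 1.793 ± 1.8 RPKM in poly(A) embryos against 1619 ± 629 RPKM in RiboMinus embryos, his-2, at 1.232 ± 0.735 against 538.4 ± 415 RPKM, his-4, at 0.817 ± 0.259 against 442.6 ± 379 RPKM, and his-62, at 60.64 ± 12.2 against 11680 ± 3854 RPKM. Of 57 histones, 55 fell, his-41 rose and his-37 was not called (55 lower and 2 higher adjusted over the list alone; median -3.68; camera adjusted p = 2.39e-41, or adjusted p = 0.0028 with an estimated correlation; his-41 and his-37 named after their values were seen). The abundant members his-59, at 92.88 ± 1.56 against 6437 ± 3869 RPKM, and his-60, at 95.56 ± 28.3 against 3004 ± 1148 RPKM, also fell, with single values uncertain because of near-identical copies. The largest rises were those of W04C9.4, at 408.6 ± 186 against 7.612 ± 4.46 RPKM, Y41E3.8, at 265.8 ± 220 against 11.15 ± 11.9 RPKM, K01G5.8, at 205.5 ± 27.7 against 8.154 ± 3.65 RPKM, and W02D3.12, at 132.0 ± 45.1 against 5.254 ± 1.19 RPKM. Without poly(A) embryo replicates 1 and 2, the call of Y41E3.8 ended (log2 difference 3.67, adjusted p = 0.0555).

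Ribosomal protein mRNAs stood higher in the poly(A) libraries: 56 of 73 rose (60 adjusted over the list alone; median 1.59; camera adjusted p = 2.98e-15, or adjusted p = 0.237 with an estimated correlation). Examples were rps-25, at 609.7 ± 396 against 145.5 ± 17.5 RPKM, and rps-1, at 322.0 ± 102 against 148.7 ± 10.2 RPKM. The gene rps-4, at 318.2 ± 180 against 119.5 ± 9.78 RPKM, was not called (adjusted p = 0.0502), but was without poly(A) embryo replicate 3 (1.89), with replicate number as a block (adjusted p = 0.0498), with an RPKM of at least 5 in 3 libraries (adjusted p = 0.0415) and with 12 separate libraries (1.46). The call of rps-1 ended after median centring (1.06, adjusted p = 0.0522) and quantile normalization (0.61). It also ended without RiboMinus replicate 3 (1.01, adjusted p = 0.0581), without RiboMinus replicates 1 and 2 (1.14, adjusted p = 0.0529) or without poly(A) embryo replicates 1 and 2 (0.75), and that of rps-25 without RiboMinus replicate 3 (1.77, adjusted p = 0.0832) or replicates 1 and 2 (2.02, adjusted p = 0.075). Of 29 germ granule and small RNA pathway genes 14 fell (14 adjusted over the list alone; median -0.95; camera adjusted p = 1.72e-06, or adjusted p = 0.0793 with an estimated correlation). They included hrde-1, at 250.7 ± 6.8 against 765.7 ± 195 RPKM. The level of wago-1 was 513.3 ± 120 against 805.0 ± 232 RPKM, and pgl-1, at 531.2 ± 340 against 213.0 ± 78.3 RPKM, was not called, but was without poly(A) embryo replicate 3 (1.9, adjusted p = 0.0114). Of 34 oocyte and early embryo genes 10 fell and 3 rose (10 and 3 adjusted over the list alone; median -0.83; camera adjusted p = 0.00101, or adjusted p = 0.492 with an estimated correlation). Those that rose were cey-2, at 6201 ± 285 against 1513 ± 65.6 RPKM, par-5, at 4556 ± 1277 against 1724 ± 316 RPKM, and pal-1 (named after its values were seen); par-5 was not called after quantile normalization (0.76). The Notch receptor gene glp-1 fell, at 104.7 ± 21.3 against 264.3 ± 94.9 RPKM, a call that ended without RiboMinus replicates 1 and 2 (-0.92) or without poly(A) embryo replicates 1 and 2 (-1.09, adjusted p = 0.0637). Neither pos-1, at 2544 ± 542 against 3301 ± 530 RPKM, nor oma-1, at 238.2 ± 66.6 against 334.6 ± 79.4 RPKM, nor mex-5, at 567.9 ± 364 against 1395 ± 1040 RPKM, was called. After quantile normalization oma-1 (-1.34) and wago-1 (-1.67) were called lower, and 16 members of this list were lower and 1 higher.

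No member of the 28 major sperm protein genes, of the 30 sperm function genes or of the 4 male soma genes was called by limma (camera adjusted p = 0.252, 0.951 and 0.953), and the median of sperm function genes was 0.01, or -0.04 after quantile normalization. However, limma-voom on recovered reads, chosen after seeing the data, called 12 major sperm proteins and 7 sperm function genes lower, at medians of -2.74 and -1.16. This method adds the same part of a read to every sample. Genes at or near 0 reads in both groups can thus come out lower in the far deeper poly(A) libraries. These calls therefore cannot show a fall. Summed over the major sperm proteins, poly(A) embryos held 2.452 ± 2.44 RPKM and RiboMinus embryos 4.627 ± 2.63 RPKM. The gene msp-3 was at 0.0534 ± 0.0755 RPKM in poly(A) embryos and listed at 0 in RiboMinus embryos, as was spe-11 at 0.0122 ± 0.00378 RPKM. The vitellogenins vit-6, at 0.145 ± 0.166 against 4.938 ± 0.141 RPKM, and vit-2, at 0.045 ± 0.0324 against 4.227 ± 0.526 RPKM, fell, but not with a pseudocount of 5 (-0.95 and -0.87; 2 adjusted over the list alone; camera adjusted p = 0.00306, or adjusted p = 0.227 with an estimated correlation). Of 22 cuticle genes 7 fell, including col-119 at 0.0512 ± 0.0112 against 1.796 ± 0.666 RPKM, and 0 with a pseudocount of 5 (7 adjusted over the list alone; camera adjusted p = 0.00141, or adjusted p = 0.241 with an estimated correlation). Of 22 muscle genes, mlc-2, at 15.95 ± 2.44 against 6.403 ± 1.42 RPKM, and pat-10, at 14.78 ± 3.14 against 2.165 ± 1.09 RPKM, rose (camera adjusted p = 0.787). The call of mlc-2 ended after quantile normalization (0.99) and with a pseudocount of 5 (0.88). Of 24 neuron genes, snb-1 (log2 difference 1.18), sbt-1 and ric-4 rose (camera adjusted p = 0.253), and the call of snb-1 ended without poly(A) embryo replicates 1 and 2 (0.95) and after quantile normalization (0.76). Of 12 eggshell genes, cbd-1, egg-1 and chs-1 fell (camera adjusted p = 0.117), and cpg-2, at 1885 ± 946 against 1161 ± 416 RPKM, was not called, but was without poly(A) embryo replicate 3 (1.18, adjusted p = 0.0384). Of 18 intestine genes cpr-1 fell (camera adjusted p = 0.787; list median 0.04, or -0.06 after quantile normalization). Of 11 early zygotic genes ceh-51, listed at 0 in RiboMinus embryos, rose to 1.206 RPKM (camera adjusted p = 0.314). The gene ref-1, at 13.76 ± 0.883 against 7.165 ± 2.13 RPKM, was not called, but was without RiboMinus replicate 3 (1.15, adjusted p = 0.0059). The genes sbt-1, ric-4, cbd-1, egg-1, chs-1, cpr-1 and ceh-51 were named after their values were seen, and the counts adjusted over the list alone were the same in these 5 lists.

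The comparison called 1328 genes higher and 950 lower of 11041 in poly(A) embryos (limma; 58.3% higher). Quantile normalization gave 992 and 1079 (47.9% higher). The calls rested on the spread pooled over the 4 groups: with only the libraries of this comparison limma called 0 genes, at a smallest adjusted p of 0.154, although 2426 genes had an unadjusted p under 0.05. On simulated data the pooled fit gave 173 false calls among 10722 unchanged genes here, so its adjusted p-values may be too small. Without poly(A) embryo replicate 3 the count of lower genes was 1628.

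Sperm-restricted mRNAs were followed into the embryo because the series asks which paternal RNAs reach the zygote. A gene was called sperm-restricted where RPKM was at least 10 in both the high-purity CB4856 sperm and the fog-2 sperm library and under 1 in each maternal-strain worm library. Of 1578 such genes, 50 (3.17%, exact 95% interval 2.36 to 4.16) had an RPKM of at least 1 in all 3 poly(A) embryo libraries, while 618 were listed at 0 in all 3 and 1127 (71.4%) were under 0.1 in all 3. Among 4594 comparison genes with no such sperm expression, 112 (2.44%, 2.01 to 2.93) were detected, an odds ratio of 1.31 (two-sided Fisher's exact test across genes, which are not independent replicates, p = 0.121). Without embryo replicate 3 the numbers were 70 (4.44%) against 144 (3.13%), with an odds ratio of 1.43 and a Fisher's exact p of 0.0167. Without embryo replicates 1 and 2 they were 67 (4.25%) against 178 (3.87%), with an odds ratio of 1.1 (Fisher's exact p = 0.502). In RiboMinus embryo libraries the order turned, at 15 (0.95%) against 62 (1.35%), with an odds ratio of 0.7 (Fisher's exact p = 0.239). The comparison set was chosen after seeing the data, since the planned one held 0 genes.

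The mRNAs most abundant in sperm mostly stood near 0 RPKM in embryos. RPKM is relative to the reads of each library. A small amount of sperm mRNA in a whole embryo could therefore stay under the bound of 1 RPKM. Of the 100 sperm-restricted mRNAs with the highest sperm level, 1 was detected, against 6 of the next 300, 17 of the next 400 and 26 of the last 778. The sperm protein gene msp-57 was at 6971 RPKM in high-purity sperm, 1655 in fog-2 sperm and 0.0154 ± 0.00528 in poly(A) embryos. The sperm chromatin gene spch-3 was at 3762 RPKM in high-purity sperm and 0.00321 ± 0.00454 in embryos, and F58A6.9 at 5220 and 0.135 ± 0.191 RPKM. The gene msp-10, at 5641 RPKM in high-purity sperm, was listed at 0 in every embryo library. These 4 were named after their values were seen. Summed over the major sperm proteins, embryos held 2.452 ± 2.44 RPKM, maternal-strain worms 32.93 ± 1.12 RPKM and high-purity sperm 114700 RPKM. Summed over all sperm-restricted genes, poly(A) embryos held 362.6 ± 32.5 RPKM, 0.101% of the 360400 RPKM in high-purity sperm, and maternal-strain worms held 165.5 ± 0.0391 RPKM. CB4856 worms held 11070 ± 88.2, low-purity sperm 185600 and fog-2 sperm 207700 RPKM. RiboMinus embryos held 2684 ± 1631 RPKM, of which 177.7 ± 66.2 remained without histone genes.

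The 10 sperm-restricted mRNAs highest in embryos were led by icmt-1, the gene of a protein carboxyl methyltransferase, at 29.84 ± 24.2 RPKM in embryos, 0.0142 ± 0.02 in maternal-strain worms and 171.9 in high-purity sperm. Its level was 12.74 RPKM in embryo replicates 1 and 2 and 46.93 in replicate 3. F18A11.3 was at 17.11 ± 6.12 RPKM in embryos and 31.95 in high-purity sperm. The histone gene his-57 was at 13.11 ± 3.6 RPKM in poly(A) embryos, 1989 ± 1241 in RiboMinus embryos and 18.74 in high-purity sperm, again with uncertain sharing of reads between copies. F44E2.9 was at 12.63 ± 10.8 RPKM in embryos and 24.48 in high-purity sperm. The other 6 were T21C12.8 at 7.909 ± 4.18 RPKM in embryos, rsa-1, a centrosomal phosphatase subunit gene, at 7.679 ± 9.5, R05D7.7 at 7.03 ± 5.06, snpc-1.3, a small nuclear RNA activating complex gene, at 6.911 ± 2.14, fbxa-108 at 6.482 ± 2.12, and Y51H4A.22 at 4.615 ± 4.77 RPKM. As a percent of high-purity sperm, these 10 ranged from 17.4 for icmt-1 to 69.9 for his-57. For rsa-1 the level was 0.96 RPKM in embryo replicates 1 and 2 and 14.4 in replicate 3. Maternal level and detection went together: 32 of the 50 detected genes had a mean above 0.3 RPKM in maternal-strain worms, and of 415 sperm-restricted genes at 0 there, 0 were detected.

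**Figure D2:**
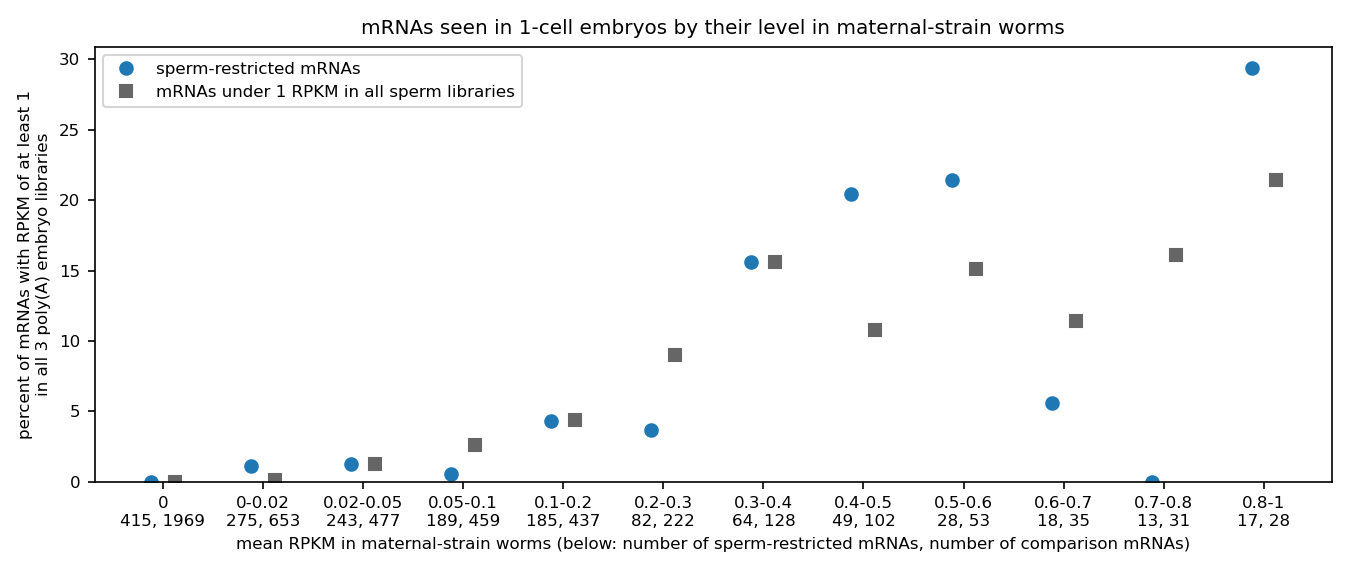
Percent of mRNAs with an RPKM of at least 1 in all 3 poly(A) embryo libraries (vertical axis) by mean RPKM in maternal-strain worms (horizontal axis), for sperm-restricted mRNAs (circles) and mRNAs under 1 RPKM in all sperm libraries (squares), with the numbers of genes below the axis. Detection was 0 of 415 and 0 of 1969 genes at a maternal level of 0, and 5 of 17 and 6 of 28 in the highest bin, which like the bins of 18 and 13 genes is thinly filled.

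The sperm libraries of low and high purity were compared to see which mRNAs differed with purification; with 1 library each, there is no replicate check. Yolk mRNAs were lower and sperm mRNAs higher in the high-purity library. The 6 vitellogenins had a median of 27.64 RPKM in high-purity and 210.6 RPKM in low-purity sperm, a median log2 difference of -3.42 that lay at percentile 0.0 of 10000 expression-matched random lists. The 30 major sperm proteins had medians of 4126 and 1368 RPKM, all 30 were higher in the high-purity library, and their median log2 difference of 1.56 lay at percentile 100. Sperm function genes (0.82, percentile 100) and muscle genes (0.73, percentile 99.86) were also higher, and oocyte genes (-0.5, percentile 0.09), intestine genes (-0.69, percentile 0.13) and eggshell genes (-0.52, percentile 1.46) lower. The other lists were histones (0.22, percentile 99.88), male soma (0.45, 99.25), neuron (0.03, 82.4), ribosomal protein (0.56, 56.13), early zygotic (-0.36, 27.27), cuticle (-0.14, 7.82) and germ granule genes (-0.33, 6.51). Of 3209 genes with at least 50 RPKM in one of these libraries, 566 were at least 2-fold higher and 283 at least 2-fold lower in the high-purity library. The largest differences upward were those of C27B7.9, at 51.43 against 2.513 RPKM, C45B2.1, at 51.64 against 4.097, Y47D7A.11, at 74.68 against 6.334, nlp-27, a peptide gene of the hypodermis, at 96.21 against 12.16, and C17F3.3, at 268.1 against 35.48 RPKM. Downward they were clec-210, a C-type lectin gene, at 2.182 against 87.69 RPKM, K07B1.8, at 24.32 against 612.7, acox-1.6, an acyl-CoA oxidase gene, at 9.538 against 199.3, F16G10.15, at 1.93 against 51.39, and comt-4, at 27.02 against 444.9 RPKM. Across 14292 genes, which are not independent replicates, Spearman's rho was 0.924 between the high-purity and low-purity libraries, 0.874 between the high-purity and fog-2 libraries and 0.923 between the low-purity and fog-2 libraries.

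Small RNAs of sperm, oocytes and embryos were compared to ask which germ cell's small RNAs the zygote carries; each group is a single library, so that no difference has a replicate check, and intervals and floors cover counting error only. Reads antisense to exons, the class that holds the 22G-RNAs bound by Argonautes, made up 75.29% of class-table reads in sperm (exact 95% interval 75.26 to 75.32), 82.05% in oocytes (82.02 to 82.07), 55.53% in hybrid embryos (55.49 to 55.58) and 81.43% in TX189 embryos (81.41 to 81.45), but 22.78% in CB4856 worms (22.73 to 22.84) and 26.92% in maternal-strain worms (26.86 to 26.97). Class-table reads leave out the sense reads of mature miRNAs, so that these shares are not of all small RNAs. Reads antisense to introns made up 41.81% in CB4856 worms and 27.79% in maternal-strain worms. Without introns the exon antisense share was 40.47% and 38.11% in these worms, so that the order of the strains turned. Reads on snoRNAs made up 20.2% in hybrid embryos (20.17 to 20.23) and 4.57% in oocytes (4.56 to 4.59). They made up 0.18% in sperm (0.18 to 0.18) and 0.05% in TX189 embryos (0.05 to 0.05). The piRNAs of the worm, 21U-RNAs, made up 4.92% in sperm (4.9 to 4.93), 1.4% in oocytes (1.39 to 1.41), 0.98% in hybrid embryos (0.97 to 0.99), 1.91% in TX189 embryos (1.9 to 1.92), 13.28% in CB4856 worms (13.23 to 13.32) and 24.02% in maternal-strain worms (23.97 to 24.08).

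MicroRNAs separated sperm from oocytes. The miR-35 to miR-42 family, needed for embryonic development, summed to 284000 RPM (of miRNA reads) in oocytes, 218000 in hybrid embryos, 207700 in TX189 embryos and 1555 in sperm. In RPM of precursor reads the sums were 544000, 175700, 88030 and 8163, from tables of only 750, 2251 and 363 sense reads, and fewer in sperm. The let-7 family summed to 105200 in sperm, 2080 in oocytes, 242.6 in hybrid embryos and 5775 in TX189 embryos, and was higher in whole worms than in sperm (169300 in CB4856 and 213000 in maternal-strain worms). The miR-58 family summed to 716900 in sperm, 18350 in oocytes, 129300 in hybrid embryos and 211500 in TX189 embryos, most of it miR-58-3p, at 704100 in sperm, 11450 in oocytes, 114800 in hybrid embryos and 204500 in TX189 embryos. The muscle-expressed miR-1-3p was at 19900 in sperm, 82.26 in oocytes, 942.4 in hybrid embryos and 5604 in TX189 embryos. The developmental timing miRNAs let-7-5p and lin-4-5p were at 8509 and 317.7 in sperm, 376.1 and 58.76 in oocytes and 27.82 and 2.225 in hybrid embryos and 452.5 and 4.229 in TX189 embryos. In the same order miR-71-5p was at 9468, 2311, 1345 and 8518. Within the family, miR-35-3p was at 99520 in oocytes, 71650 in hybrid embryos and 884.1 in sperm, and miR-40-3p at 57490, 38250 and 27.77. The others went from oocytes through hybrid embryos to sperm as 17570, 17100 and 30.22 for miR-36-3p and 42520, 38140 and 211.9 for miR-37-3p. Next came 959.8, 2748 and 113.5 for miR-38-3p, 63450, 43110 and 198.5 for miR-39-3p, 111.6, 170.8 and 1.633 for miR-41-5p, and 160.6, 815.6 and 75.95 for miR-42-3p. In TX189 embryos miR-35-3p, at 159900, made up most of the family sum. The others there differed from hybrid embryos in both directions: miR-36-3p was at 2757, miR-37-3p at 15700, miR-38-3p at 4889, miR-39-3p at 16410, miR-40-3p at 4546, miR-41-5p at 249.5 and miR-42-3p at 2709.

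Of 85 miRNAs with at least 100 RPM in one germ cell, 14 were at least 8-fold higher in sperm and 43 at least 8-fold higher in oocytes. The sperm-biased miRNAs summed to 848400 RPM in sperm, 14270 in oocytes, 117200 in hybrid embryos and 222100 in TX189 embryos. They also summed to 468200 in CB4856 worms and 446300 in maternal-strain worms, so that they were not limited to sperm. The oocyte-biased ones summed to 920700 in oocytes, 10710 in sperm, 571300 in hybrid embryos, 541800 in TX189 embryos, 301900 in CB4856 worms and 276900 in maternal-strain worms. Among those with the largest sperm-to-oocyte ratio, miR-1819-3p (7743 in sperm), miR-796 (670.5), miR-1822-5p (544.7) and miR-784-5p (325.0) were listed at 0 in oocytes. In hybrid embryos miR-1819-3p and miR-784-5p were also listed at 0, while miR-796 was at 5.563 and miR-1822-5p at 26.7. In TX189 embryos miR-796 was at 1430, above sperm, miR-1819-3p at 463.1, miR-1822-5p at 2.115 and miR-784-5p at 0. The let-7 relative miR-84-5p was at 74620 in sperm, 266.4 in oocytes, 15.58 in hybrid embryos and 4293 in TX189 embryos. On the oocyte side stood miR-39-5p at 1540 in oocytes against 1.633 in sperm, miR-229-5p at 7917 against 13.07, miR-1829b at 11580 against 19.6 and miR-229-3p at 850.1 against 1.633, and these were at 3991, 11230, 2709 and 6302 in hybrid embryos and 102.6, 184.0, 397.6 and 97.28 in TX189 embryos.

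For 21U-RNAs, the hybrid embryo library resembled oocytes and the TX189 embryo library resembled sperm. Of 2480 loci with at least 10 reads in one germ cell, 593 were at least 8-fold higher in sperm and 380 at least 8-fold higher in oocytes, a balance that turned to 227 and 891 when scaled to 21U reads alone. The sperm-biased loci summed to 41660 RPM (of class-table reads) in sperm, 444.1 in oocytes, 353.3 in hybrid embryos and 13520 in TX189 embryos. Hybrid embryos thus held 0.848% of the sperm sum and the oocyte library 1.07%, an order that turned to 2.03% and 1.74% when scaled to 21U reads. The oocyte-biased loci summed to 7336 in oocytes, 4636 in hybrid embryos (63.2% of the oocyte sum), 260.7 in TX189 embryos (3.55%) and 179.4 in sperm. In CB4856 worms and maternal-strain worms the sperm-biased loci summed to 38990 and 64790, or 93.6% and 156% of the sperm sum, and the oocyte-biased loci to 16160 and 31480. Scaled to 21U reads this order turned, at 16.2% and 12.6%. In that scaling TX189 embryos held 78.1% of the sperm sum instead of 32.5%, and 8.71% of the oocyte sum instead of 3.55%. Across the 2480 loci, which are not independent replicates, Spearman's rho was 0.909 between oocytes and hybrid embryos, 0.081 between oocytes and TX189 embryos and 0.674 between sperm and TX189 embryos. The locus 21UR-7645 had 10375 reads in sperm and 0 in oocytes, at least 2940-fold higher in RPM (floor of 3 reads per library), and 2 reads in hybrid embryos and 1575 in TX189 embryos. Loci 21UR-14559 and 21UR-6204, with identical values in every library and so not to be told apart, were at least 1810-fold higher in sperm, 21UR-5503 was 1540-fold higher (exact 95% interval 1170 to 2080) and 21ur-116 was 1170-fold higher (635 to 2440). In oocytes, 21ur-3506 was at least 1410-fold higher than in sperm, with 3587 reads in oocytes, 1324 in hybrid embryos and 0 in TX189 embryos. There 21UR-7225 was 1470-fold higher (263 to 58100), 21ur-38 was 632-fold higher (290 to 1720), 21ur-3085 was 404-fold higher (111 to 3340) and 21ur-609 was at least 310-fold higher.

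Small RNAs antisense to exons put TX189 embryos nearer oocytes than sperm, unlike 21U-RNAs. Across 208 mature miRNAs, Spearman's rho of TX189 embryos was 0.693 with sperm and 0.619 with oocytes. For hybrid embryos it was 0.201 and 0.687. Of 8532 genes with at least 50 reads in one germ cell, 1066 were at least 8-fold higher in sperm and 1774 at least 8-fold higher in oocytes. The sperm-biased set summed to 112400 RPM in sperm, 5031 in oocytes, 4564 in hybrid embryos (4.06% of the sperm sum, against 4.48% in oocytes) and 18400 in TX189 embryos (16.4%). Scaled to exon reads the order of hybrid embryos and oocytes turned, at 5.67% and 4.42%, and at 4-fold the set stood at 30.8% in TX189 embryos and 6.66% in hybrid embryos (189300 RPM in sperm and 18940 in oocytes). The oocyte-biased set summed to 201800 in oocytes, 152100 in hybrid embryos (75.4%), 97640 in TX189 embryos (48.4%) and 9215 in sperm. Scaled to exon reads hybrid embryos (116%) stood above oocytes. In CB4856 worms and maternal-strain worms the sperm-biased set summed to 39920 and 4119 and the oocyte-biased set to 31390 and 64260. Spearman's rho across these genes was 0.918 between oocytes and hybrid embryos, 0.835 between oocytes and TX189 embryos and 0.543 between sperm and TX189 embryos. Sperm function genes had a median log2 difference of 4.34 between sperm and oocytes over 20 members (percentile 99.99 of 10000 matched lists), ribosomal protein genes -0.23 (percentile 100) and neuron genes -0.84 (percentile 66.16). Toward oocytes, histones had -3.5 (percentile 2.54), early zygotic genes -3.63 (percentile 6.9) and eggshell genes -2.71 (percentile 2.51), while germ granule and small RNA pathway genes had -1.86 (percentile 1.27) and oocyte genes -1.77 (percentile 7.5). The largest sperm-biased targets were T13F3.8, with 8018 reads in sperm, 1 in oocytes and 1 in hybrid embryos (6810-fold, exact 95% interval 1220 to 269000), F47B3.7 (3560-fold, 639 to 141000), msrp-2 (1730-fold, 478 to 14300), the acyltransferase gene oac-56 (1300-fold, 595 to 3530) and the kinase gene kin-26 (1230-fold, 478 to 4500). Among the 5 largest oocyte-biased targets were ekl-5, with 3838 reads in oocytes, 2950 in hybrid embryos, 135 in TX189 embryos and 1 in sperm (4520-fold, 811 to 179000), F54E4.2, with 3657 reads in oocytes, 2934 in hybrid embryos and 0 in sperm (at least 1440-fold), Y58A7A.2 (752-fold, 257 to 3650) and lgc-40, a ligand-gated channel gene (437-fold, 170 to 1610).

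**Figure D3:**
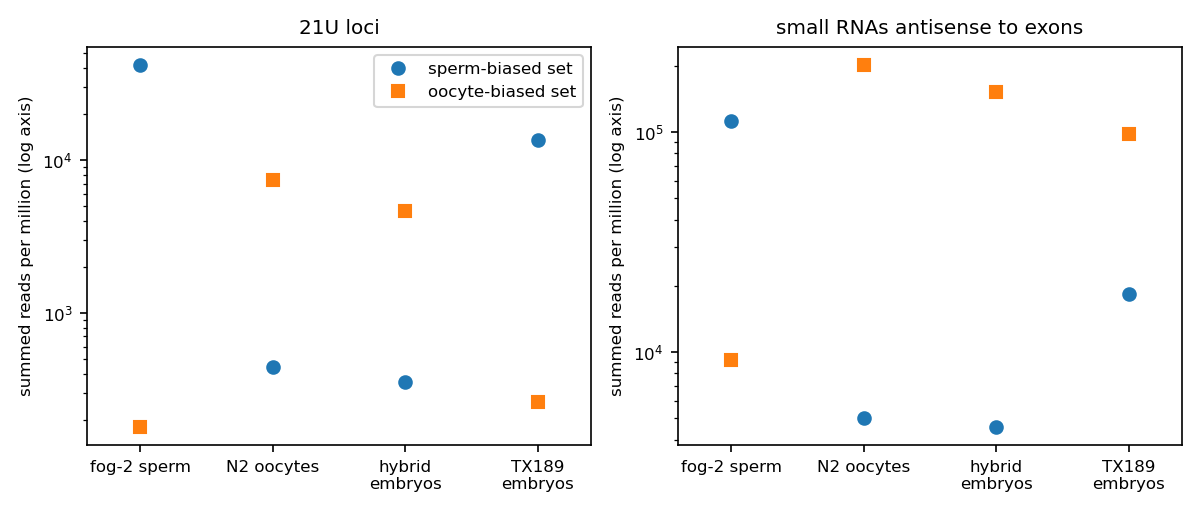
Summed RPM (log axis) of sperm-biased (circles) and oocyte-biased (squares) sets in 4 single libraries, for 21U loci on the left and small RNAs antisense to exons on the right. For 21U loci the sperm-biased sum was 353.3 in hybrid embryos and 13520 in TX189 embryos, while the oocyte-biased sum was 4636 and 260.7.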

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

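Of the tests below, those on sperm RNA mixed in and on strain were chosen only after the result was seen, and the snoRNA test before.

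Signal was found in deposited data that the comparisons did not use. Among 1916 mRNA features without a gene name, 113 had an RPKM of at least 1 in all 3 poly(A) embryo libraries, and 27 an RPKM of at least 10. Small RNA columns that match no sample also held 21U reads: loci with a sense value numbered 8904 in NR_2, 8331 in NR_3, 8485 in HW_2 and 7069 in HW_3. Across loci, Spearman's rho with the maternal-strain and CB4856 worm columns was 0.892 and 0.777 for NR_2, 0.651 and 0.56 for NR_3, 0.784 and 0.858 for HW_2, and 0.551 and 0.607 for HW_3. No group had the 4 samples needed to test for a sample far from the others.

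The 21U profile of the TX189 embryo library lay near that of sperm, while the hybrid library lay near oocytes. On mature miRNAs the rho of TX189 embryos was also highest with sperm, by less. It was 0.693 with sperm, 0.619 with oocytes and 0.504 with hybrid embryos. For the loss of oocyte-biased loci the tables argued against 2 explanations, each as the whole cause. If sperm RNA had been mixed into an embryo sample with the profile of the hybrid library, the oocyte-biased 21U sum would need 98.2% sperm reads. The sperm-biased 21U sum needed only 31.9%, and the oocyte-biased and sperm-biased exon sums 38.1% and 12.8%. Scaled to the reads of each class these shares lay nearer, at 92.8%, 77.7%, 59.1% and 11.2%, but still apart. Against a strain difference brought by the CB4856 fathers, the rho of N2 oocytes was 0.081 with TX189 embryos, of N2 background. It was 0.909 with hybrid embryos, whose fathers were CB4856. On exons the rho was 0.835 and 0.918. The labels also give fem-1(hc17ts) for the mothers of hybrid embryos but not for TX189 embryos. An effect of this mutation cannot be told apart from other differences between these libraries and was not tested. For the gain of sperm-biased loci both stay open. The 31.9% on 21U loci against 12.8% on exons leaves room for a smaller share of sperm RNA. With sets at 4-fold the shares lay nearer: 33.3% for sperm-biased 21U loci, 25.9% and 26.6% for sperm-biased and oocyte-biased exons, but 96.5% for oocyte-biased 21U loci. The sperm-biased sum of CB4856 worms was 60.2% of that of maternal-strain worms, but 128% when scaled to 21U reads. The rules for these explanations were changed more than once after the values were seen: on 21U loci alone both explanations were excluded, and with exons required to show an equally large difference neither was. A difference between library preparations is a further candidate explanation: across 114 snoRNAs, TX189 embryos had a rho of 0.797 with sperm and 0.615 with hybrid embryos. However, the snoRNA rho was 0.954 between hybrid embryos and oocytes and 0.587 between sperm and oocytes. As snoRNA profiles also differed between the germ cell libraries, they cannot tell a difference in preparation from one in cell content. A biological difference between the embryos was not tested.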

How the results depend on the processing

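Tests with 12 separate libraries, limma-voom, and RiboMinus detection without histones were chosen only after seeing the data; the planned edgeR fit was not run. Where the construction of an alternative does not give it, the cause was not tested. For CB4856 against maternal-strain worms, higher and lower calls (1463 higher) became 587 and 84 with a pseudocount of 5, 713 and 118 with an RPKM of at least 5 (fewer genes tested), and 921 and 577 with quantile normalization. Leaving out each sample gave 1304 to 1348 higher and 141 to 149 lower. For poly(A) embryos against maternal-strain worms (3412 and 2692), median centring gave 1553 and 5482, a pseudocount of 5 gave 1382 lower, and leaving out each sample gave 2845 to 3644 higher and 2474 to 3030 lower. For poly(A) against RiboMinus embryos (1328 and 950), only its own libraries gave 0 higher and 0 lower with limma (2426 genes at an unadjusted p under 0.05), limma-voom gave 1539 and 1757, and leaving out each sample gave 968 to 1722 higher and 660 to 1628 lower, the last without poly(A) embryo replicate 3. A lone sample left in a group was assumed to vary like the other groups. RiboMinus libraries, at 4.56 to 13.88 M reads, limit what can be called for rare mRNAs.

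With replicate number as a block, which 2 pairs cannot establish as a pairing (correlation of replicate deviations between groups 0.082 to 0.7255), counts were 1474 and 180, 3459 and 2686, and 1341 and 931, with 20 list tests. As 12 separate libraries they were 1525 and 206, 3485 and 2859, and 1895 and 1372. Of 42 list tests, 20 passed with the preset correlation, 4 with an estimated correlation and 27 with fry. Of 2631 values of named genes under alternatives, 2506 kept their side of the threshold, 70 lost a call, 55 gained one and 0 reversed.

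Sperm-restricted mRNAs detected in embryos numbered 50, but 24 with sperm RPKM of at least 50, 4 with maternal worms under 0.1, 15 in RiboMinus libraries, 13 there without histone genes, 244 at an embryo RPKM of 0.1 and 67 to 70 on leaving out each embryo sample. The percent antisense to exons in sperm, oocytes, hybrid and TX189 embryos was 84.92, 85.91, 60.73 and 88.73 without rRNA. Without introns it was 78.83, 85.96, 60.07 and 84.34. In CB4856 and maternal-strain worms it was 25.26 and 30.16 without rRNA, and 40.47 and 38.11 without introns. The 21U percent of these worms was 23.58 and 34.01 without introns. The miR-35 to miR-42 sum of 218000 in hybrid embryos became 207700 in TX189 embryos and 175700 from precursors, where oocytes had 544000, TX189 embryos 88030 and sperm 8163, from few reads. The sperm-biased 21U percent of 0.848 became 2.03 per 21U reads (oocytes 1.07 to 1.74, with 227 sperm-biased and 891 oocyte-biased loci), 1.71 at 4-fold and 32.5 in TX189 embryos (78.1 per 21U reads); the oocyte-biased 63.2 became 94.5, 65.8 and 3.55 (8.71 per 21U reads). The sperm-biased exon percent of 4.06 became 5.67 per exon reads (oocytes 4.48 to 4.42), 6.66 at 4-fold, 4.13 at 200 counts and 16.4 in TX189 embryos (30.8 at 4-fold); the oocyte-biased 75.4 became 116.0, 73.6, 72.9 and 48.4.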

Other observations

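Of the tests below, those on proportion to sperm level, on low maternal transcription and on egg-bearing hermaphrodites were chosen only after the result was seen, and the test on deep libraries before.

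Some sperm-restricted mRNAs were seen in poly(A) embryos. The 100 most abundant stood at a median of 0.00138% of their sperm level, against 4.82% for the detected ones. The detected ones were picked by their embryo level. This gap therefore cannot decide whether sperm mRNA was carried in proportion to its level at a very small share. It shows only that a share as high as 4.82% was not shared by the 100 most abundant. Low maternal transcription of the same genes may account for the number detected, since draws of comparison genes matched on maternal RPKM gave a mean of 51.2 detected (38 to 65 in the central 95%) against 50 observed. This leaves open whether single mRNAs, such as icmt-1, came from sperm, which tables without allele values cannot show.

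Yolk mRNAs were about as abundant in CB4856 worms as in maternal-strain worms for vit-1, vit-2, vit-5 and vit-6, though not for vit-3 and vit-4. Reads from 1 deep library were argued against, since the lower CB4856 sample reached 0.993 of the higher one for vit-2. This does not cover a culture shared by the samples, as it is not known whether replicate 3 came from separately grown worms. Egg-bearing hermaphrodites among the CB4856 worms are a candidate explanation, as oocyte genes had a median log2 difference of -0.22 and eggshell genes of -0.3. The labels give no sex, and a difference between strains in yolk gene expression stays open, untested.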
